A study of Homo sapiens with 12 samples.

How the data were processed

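Gene expression was measured by RNA-seq in 12 libraries from PC-3 and C4-2 cells, which are established human prostate cancer lines. Cells received siRNA against MTHFD1L or control siRNA for 3 days, and each of the 4 groups held 3 libraries. Per the labels, total RNA was isolated with RNeasy columns, and 500 ng entered the SureSelect XT HS2 mRNA kit. The siRNAs came from Sigma-Aldrich and the transfection reagent from T-Pro. The sequences of the siRNAs and the number of siRNAs used against MTHFD1L were not given in the sources used here. Sample titles call the controls siControl, while the genotype label and the column names of the table call them WT. They were treated as control-siRNA cells here. The labels do not say whether the 3 libraries of a group came from separate cultures or from 1 culture.

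The authors trimmed reads with Trimmomatic, aligned them to GRCh38 with HISAT2 and quantified genes with StringTie. The versions of these tools were not given in the sources used here. The deposited table holds TPM, which scales each library's transcripts by length to a fixed total, for 60617 Ensembl gene identifiers in the 12 libraries, and each column sums to nearly the same total. Read counts were not used here, so the depth per library is unknown and no counting interval can be given. Gene names were matched by identifier for 60261 of the 60617, and genes without a match held at most 0.1% of any library's TPM. In all, 20643 identifiers were 0 in every library.

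Values were analysed as log2(TPM + 1). Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 19289. The model was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on 4 group means over all 12 libraries, which leaves 8 residual degrees of freedom. There were 5 comparisons, namely siMTHFD1L against siControl in PC-3, the same in C4-2, the mean of both, the PC-3 change minus the C4-2 change, and PC-3 siControl against C4-2 siControl. All tests were two-sided except the overlap tests. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Rankings of genes by fold change cover called genes with an established symbol and a mean of at least 5 TPM in a group compared. Their libraries did not overlap between the groups compared, a condition not set for the difference between the lines. The overlap of calls between the lines was tested with Fisher's exact test, one-sided. Fold changes are siMTHFD1L over siControl on the log2(TPM + 1) scale, so the added 1 shrinks the change of genes with low TPM. Errors printed with fold changes are standard errors from the model, and TPM means carry the SD of 3 libraries. In Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used to prepare the table, search sequences and draw figures.

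The comparisons, the tests, the alternatives and 40 gene lists were fixed before the data were examined. Lists were tested with camera from limma at its preset correlation of 0.01 when at least 5 members were tested, and p-values were adjusted over the 36 lists that qualified. The same test with a correlation estimated per list served as an alternative. This correlation was estimated from the residuals of all 12 libraries, so each list had the same value in every comparison. The lists covered folate enzymes, serine synthesis, methionine cycle, purine and pyrimidine synthesis, ATF4 targets, the ER unfolded protein response, G1/S and G2/M genes, p53 targets, and cyclin-dependent kinase inhibitors with senescence genes. Others covered the androgen response, luminal prostate markers, basal prostate markers, epithelial and mesenchymal genes, interferon-stimulated genes, NF-kB and cytokine genes, apoptosis regulators, immediate early genes and heat shock genes. Metabolic lists covered glycolysis, hypoxia targets, cholesterol and fatty acid synthesis, and nuclear and mitochondrial genes of the respiratory chain. They also covered mitochondrial translation and NRF2 targets. The rest covered nucleolar genes, cytosolic ribosomal proteins, lysosome and autophagy, DNA and histone methylation, homologous recombination and Fanconi genes, replication-dependent histones, and RNA interference machinery. The 4 lists with too few tested members held neuroendocrine, fibroblast, blood and immune, and endothelial markers. In all, 3 symbols of the lists had no match in the table.

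Alternatives were a pseudocount of 0.1 or 5, no filter beyond a TPM above 0, a filter at a TPM of 5, and 3 other scalings. The scalings were median-of-ratios factors, quantile normalization, and rescaling after the mitochondrial-genome genes and the 20 highest genes were left out. Further alternatives were no trend, array weights, replicate number as a block, leaving out each library in turn, only the libraries of the 2 groups compared, and a threshold of 0.01. Correlations of residuals between libraries with the same replicate number lay between -0.105 and 0.061, so replicate number was not used as a pairing in the results reported.

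The procedure was tested on simulated data with 50 changed genes per fold change, drawn from genes averaging at least 5 TPM on the log2(TPM + 1) scale. At a true change of 1.25-fold it recovered 54% of the changed genes in the PC-3 design and 42% in the C4-2 design. At 1.5-fold it recovered 88% in both, and at 2-fold 96% and 100%. It called 7 and 9 of 19089 unchanged genes. Noise was drawn separately for each gene, so a shift shared by many genes of a library, as in C4-2 siControl 2, was not simulated. Words of 7 bases were counted in annotated 3' UTRs of 12054 tested genes, from the GENCODE 29 annotation and the GRCh38 sequence. Read alignment, splicing and allele-specific expression were not analysed here, and results that need withheld genes are not reported here.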

Results

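RNA-seq libraries were made from PC-3 and C4-2 cells, which are human prostate cancer lines, after 3 days of siRNA against MTHFD1L or control siRNA. MTHFD1L is the mitochondrial synthetase that releases formate from 10-formyltetrahydrofolate. PC-3 cells lack functional p53, and C4-2 cells derive from LNCaP and carry wild-type p53. Each of the 4 groups held 3 libraries, 12 in all. The values are TPM, and the depth of each library is unknown. Of 60617 gene identifiers, 19289 were tested. The labels do not say that the libraries of a group came from separate cultures. Every p-value of a single gene below thus measures only the spread between these libraries. Those of lists and overlaps compare genes within these libraries.

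The target was measured first in every library. MTHFD1L (ENSG00000120254) lies on chromosome 6 of GRCh38 from 150865549 to 151101887 on the plus strand. In PC-3, the TPM of MTHFD1L was 55.957, 52.049 and 55.508 in siControl libraries and 26.505, 31.726 and 29.007 in siMTHFD1L libraries. The means were 54.5 ± 2.14 and 29.1 ± 2.61 (SD, n = 3). In C4-2, it was 18.767, 18.056 and 18.557 in siControl libraries and 11.899, 11.438 and 14.025 in siMTHFD1L libraries, with means of 18.5 ± 0.365 and 12.5 ± 1.38 (SD, n = 3). The log2 fold change was -0.89 ± 0.08 in PC-3 (adjusted p = 8.7e-06) and -0.54 ± 0.08 in C4-2 (adjusted p = 0.00076). The knocked-down cells thus kept 0.541 and 0.689 of the control value on the TPM + 1 scale, and all 3 siMTHFD1L libraries lay below all siControl libraries in each line. PC-3 siControl cells held 2.85 times the MTHFD1L of C4-2 siControl cells on that scale (adjusted p = 2.2e-09).

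**Figure D1:**
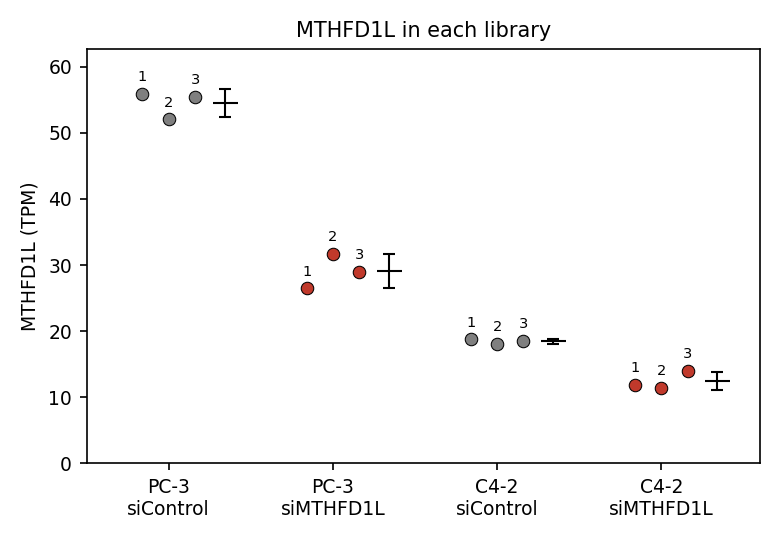
MTHFD1L in TPM (vertical axis) in each of the 12 libraries, by line and siRNA, with replicate numbers; bars give the mean ± SD of 3 libraries. The siMTHFD1L libraries lie at 26.505 to 31.726 in PC-3 and at 11.438 to 14.025 in C4-2, below every siControl library of the same line.

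The comparison in PC-3 asks what MTHFD1L knockdown changes in a line without p53 function. The largest increases included genes of inflammatory signalling. PTGS2, which encodes cyclooxygenase 2, went from 2.37 to 21.8 TPM, and IL1RL1, the receptor of interleukin 33, went from 37.3 to 188. The cytokines IL24 and CSF2 rose from 2.17 to 14.0 and from 1.89 to 8.81 TPM. Mitotic genes rose with them, among them AURKB and KIF2C, a kinase and a kinesin of the spindle, at 5.02 to 26.4 and 16.3 to 66.4 TPM. Among the decreases were BST2, an interferon-induced membrane protein, from 171 to 50.1 TPM, and GRPR, the gastrin-releasing peptide receptor, from 41.9 to 10.1. CYB5A, an electron donor in lipid and steroid metabolism, fell from 22.4 ± 1.76 to 5.11 ± 0.871 TPM (SD, n = 3).

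In PC-3, 6323 genes passed an adjusted p of 0.05, of which 3285 were higher and 3038 lower after knockdown. That balance turned under each of the 3 other scalings, with 3150 higher and 3373 lower under median-of-ratios factors, 2942 and 3246 under quantile normalization, and 2862 and 3501 after rescaling without the highest and mitochondrial-genome genes. Of these, 410 changed by at least 1 on the log2 scale, 251 upward and 159 downward. The largest log2 increases among genes with a mean of at least 5 TPM were PTGS2 (ENSG00000073756, chromosome 1, 186671791 to 186680427) at 2.76 ± 0.10 with adjusted p = 2.8e-08, IL1RL1 at 2.31 ± 0.08 and DIO3 at 2.30 ± 0.34. IL24 at 2.26 ± 0.12 and AURKB at 2.18 ± 0.11 (adjusted p = 1.9e-07) came next. The largest decreases were MS4A7 at -2.17 ± 0.07, CYP2B6 at -2.12 ± 0.08, the AP-1 subunit FOSB at -1.97 ± 0.50 (adjusted p = 0.0094), GRPR at -1.95 ± 0.10 and CYB5A at -1.94 ± 0.11 (adjusted p = 2.7e-07). MS4A7, FOSB, CYB5A and IL1RL1 carry the bases TCACTTG in the 3' UTR, which the closing section takes up. With a pseudocount of 5 in place of 1, DIO3, IL24, CSF2, MS4A7 and CYP2B6 moved to 1.38, 1.41, 1.01, -1.21 and -1.08, and all of these calls held.

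Of the 36 lists, 20 were called in PC-3 with the preset correlation, and G1/S genes alone kept the call with a correlation estimated per list. The estimate was -0.016 for G1/S genes, below the preset value, and 0.84 for G2/M genes, 0.56 for ATF4 targets and 0.53 for nucleolar genes. Other lists lost the call at low estimates, such as 0.032 for epithelial genes and for mitochondrial translation. The estimates include C4-2 siControl 2, so a kept or lost call does not rank the lists by their spread in PC-3 alone. Of 42 G2/M genes, 41 rose and 1 did not pass, with a median log2 fold change of 1.49 (adjusted p = 1.7e-21, and adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone, 41 rose and 1 fell. The cyclin-dependent kinase CDK1 rose by 1.66 ± 0.12 and AURKB by 2.18 ± 0.11. Of 42 G1/S genes, which license and copy DNA, 28 rose and 14 did not pass, and adjusted over the list alone 31 rose and 1 fell (median 0.40, adjusted p = 3.8e-10, and 0.0017 with an estimated correlation). FEN1, a flap endonuclease, rose by 0.65 ± 0.06 and the helicase subunit MCM7 by 0.51 ± 0.05. Of 25 homologous recombination and Fanconi genes, 18 rose, 1 fell and 6 did not pass, or 19 and 1 adjusted over the list alone (median 0.74, adjusted p = 1.5e-07, and 0.23 with an estimated correlation). FANCA rose by 0.85 ± 0.07. That median was 0.46 with a pseudocount of 5.

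Interferon-stimulated genes fell in PC-3, where 1 of 32 rose, 24 fell and 7 did not pass (2 and 25 adjusted over the list alone). Their median was -0.49 (adjusted p = 2.7e-11, and 0.052 with an estimated correlation), and the antiviral genes MX2 and IFI6 changed by -0.86 ± 0.06 and -0.84 ± 0.07. Of 26 NF-kB and cytokine genes, 13 rose, 4 fell and 9 did not pass, or 14 and 4 adjusted over the list alone (median 0.42, adjusted p = 0.0022, and 0.23 with an estimated correlation). The interleukins IL1B and IL6 rose by 1.51 ± 0.07 and 0.60 ± 0.05, and the list's median was 0.24 with a pseudocount of 5. Of 23 immediate early genes, 12 rose and 5 fell (13 and 5 adjusted over the list alone, median 0.35, adjusted p = 0.015, and 0.24 with an estimated correlation), with FOSL1 at 1.63 ± 0.06. That call ended at a filter of 5 TPM (adjusted p = 0.060). Of 18 epithelial genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone, median -0.27, adjusted p = 0.00021, and 0.096 with an estimated correlation), among them the splicing factor ESRP2 at -0.33 ± 0.05.

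Cholesterol synthesis genes rose in PC-3, where 18 of 25 were higher, 2 lower and 5 did not pass (19 and 2 adjusted over the list alone). The median was 0.32 (adjusted p = 3.8e-07, and 0.12 with an estimated correlation). INSIG1, the sterol sensor of the pathway, rose by 1.18 ± 0.05 from 28.0 to 64.9 TPM, and the synthase FDPS rose by 0.61 ± 0.04. Of 28 ATF4 targets, 15 rose and 13 did not pass (17 rose adjusted over the list alone, median 0.33, adjusted p = 1.6e-05, and 0.42 with an estimated correlation), with the stress factor DDIT3 at 0.77 ± 0.15. Of 27 NRF2 targets, 16 rose, 3 fell and 8 did not pass, or 18 and 3 adjusted over the list alone (median 0.29, adjusted p = 0.00011, and 0.23 with an estimated correlation). Of 13 mRNAs of the mitochondrial genome, 10 fell and 3 did not pass (11 fell adjusted over the list alone, median -0.28, adjusted p = 0.00017, and 0.33 with an estimated correlation), with MT-CYB at -0.52 ± 0.08. Their call ended with quantile normalization (adjusted p = 0.14). Of 58 nuclear respiratory chain genes, 22 rose and 1 fell (24 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.00021, and 0.23 with an estimated correlation). Of 17 heat shock genes, 1 rose and 8 fell (1 and 10 adjusted over the list alone, median -0.23, adjusted p = 0.00065, and 0.23 with an estimated correlation), with the chaperone HSPA1A at -0.61 ± 0.04.

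Further lists were also called in PC-3. Of 26 nucleolar genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.20, adjusted p = 0.0025, and 0.53 with an estimated correlation), with the growth regulator MYC at 1.00 ± 0.15. Of 37 mitochondrial translation genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.0035, and 0.23 with an estimated correlation). Glycolysis had 7 of 23 higher (median 0.15, adjusted p = 0.0090, and 0.47 with an estimated correlation), and adjusted over the list alone 7 rose and 1 fell. Purine synthesis had 5 of 13 higher, the same number adjusted over the list alone (median 0.18, adjusted p = 0.015, and 0.24 with an estimated correlation). Fatty acid synthesis had 7 of 16 higher and 1 lower (8 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.015, and 0.23 with an estimated correlation). Histones had 5 of 16 higher and 2 lower (6 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.018, and 0.23 with an estimated correlation), a call that ended at a filter of 5 TPM (adjusted p = 0.12). Lysosome and autophagy genes had 3 of 30 higher and 15 lower, the same adjusted over the list alone (median -0.12, adjusted p = 0.048, and 0.45 with an estimated correlation). That call also ended without PC-3 siControl 1 (adjusted p = 0.077) and without PC-3 siMTHFD1L 1, 2 or 3 (0.068, 0.057 and 0.060).

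Among the folate enzymes of PC-3, the mitochondrial dehydrogenase MTHFD2 rose by 0.53 ± 0.12 (adjusted p = 0.0044), the serine hydroxymethyltransferase SHMT2 by 0.32 ± 0.04 (adjusted p = 8.6e-05) and the folate carrier SLC25A32 by 0.25 ± 0.04 (adjusted p = 0.0012). Thymidylate synthase, TYMS, rose by 1.39 ± 0.08. The cytosolic enzyme MTHFD1, whose 3' UTR holds TCACTTG, was not called at -0.01 ± 0.07 (adjusted p = 0.97). The folate list as a whole was not called in PC-3, with 9 of 26 higher and 5 lower (10 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.20). Targets of p53 were not called either, with 2 of 25 higher, 3 lower and 20 not passing (2 and 3 adjusted over the list alone, median -0.01, mean 0.01, adjusted p = 0.99).

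The comparison in C4-2 asks the same of a line with p53. HMOX1, the haem oxygenase induced by oxidative stress, rose from 78.2 to 391 TPM, and the NRF2 target OSGIN1 from 7.62 to 24.3. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases, rose from 211 to 663 TPM, and the p53 target DDB2, a DNA damage sensor, from 27.4 to 78.0. ADRA2A, an adrenergic receptor, fell from 90.3 to 13.7 TPM, and ADAM9, a membrane metalloprotease, from 324 to 122. The prostate kallikreins KLK3 and KLK2 fell from 5144 to 3890 and from 741 to 375 TPM. CYB5A fell from 101 to 25.4 TPM, and SYT4, a synaptotagmin of vesicle release, from 127 to 41.1.

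In C4-2, 5832 genes were called, 3810 higher and 2022 lower, and 155 changed by at least 1 on the log2 scale, 92 upward and 63 downward. Under median-of-ratios factors 2856 were higher and 2744 lower, and under quantile normalization 2860 and 2823. After rescaling without the highest and mitochondrial-genome genes, 3446 were higher and 2252 lower. Among genes with a mean of at least 5 TPM, the largest log2 increases were HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) at 2.37 ± 0.19 with adjusted p = 2.5e-05, CCL20 at 1.78 ± 0.45, CDKN1A at 1.71 ± 0.18 (adjusted p = 0.00012), DDB2 at 1.60 ± 0.25 and OSGIN1 at 1.59 ± 0.14. The largest decreases were ADRA2A at -2.46 ± 0.34 (adjusted p = 0.00054), CYB5A at -1.95 ± 0.11, FOSB at -1.94 ± 0.50, FOS at -1.71 ± 0.39 and GRIN3A at -1.59 ± 0.31. ADAM9 changed by -1.39 ± 0.05 (adjusted p = 5.1e-08). Of these, CCL20, CYB5A, FOSB and ADAM9 hold TCACTTG in the 3' UTR. The call of CCL20 (adjusted p = 0.012) ended without C4-2 siControl 1 (0.052) and without siControl 3 (0.051), and that of FOSB (adjusted p = 0.013) without siControl 1 (0.057) and without siControl 3 (0.056). CCL20 and FOSB moved to 0.76 and -1.16 with a pseudocount of 5.

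The control libraries of C4-2 were not alike. In C4-2 siControl 2, the median of the G2/M list lay 0.92 above its level in siControl 1 and 3, while the siMTHFD1L libraries lay 1.16 above those 2. The count of genes called in C4-2 was 8766 without siControl 2, 3571 without siControl 1 and 3633 without siControl 3.

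**Figure D2:**
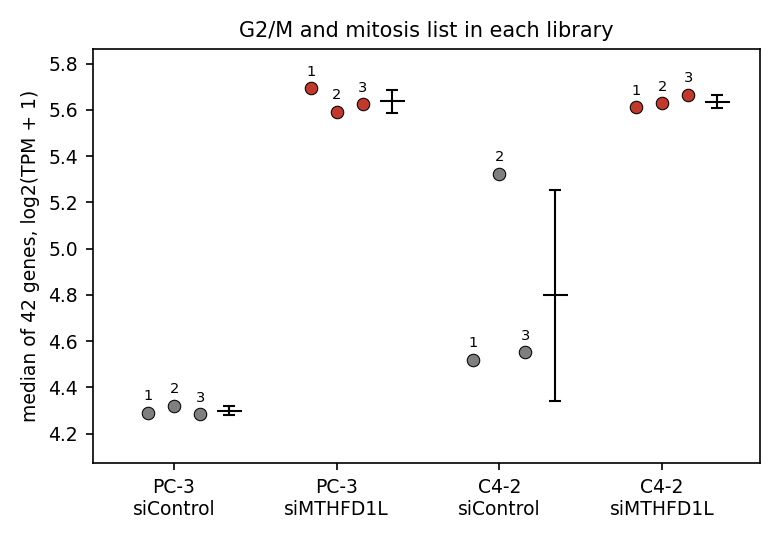
Median log2(TPM + 1) of the 42 genes of the G2/M list (vertical axis) in each of the 12 libraries, by line and siRNA, with replicate numbers; bars give the mean ± SD of 3 libraries. The C4-2 siControl libraries lie at 4.52, 5.32 and 4.55, and the C4-2 siMTHFD1L libraries at 5.61 to 5.67.

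In C4-2, 19 lists were called with the preset correlation, and no list kept its call with an estimated one, where the lowest adjusted p was 0.23. Of 26 nucleolar genes, 21 fell and 5 did not pass, and adjusted over the list alone 22 fell (median -0.52, adjusted p = 5.0e-16, and 0.23 with an estimated correlation). The RNA polymerase I subunit POLR1A, at -0.76 ± 0.07, and NIP7 and DKC1 of ribosome assembly, at -0.69 ± 0.07 and -0.51 ± 0.06, hold TCACTTG in the 3' UTR, and UTP20 of the same pathway, at -0.52 ± 0.07, does not. In siControl 2, the nucleolar median already lay at -0.37 against siControl 1 and 3. Of 42 G2/M genes, 38 rose and 4 did not pass, and adjusted over the list alone 39 rose (median 0.85, adjusted p = 2.0e-11, and 0.37 with an estimated correlation), with the phosphatase CDC25B at 1.05 ± 0.11. Of 25 p53 targets, 18 rose, 1 fell and 6 did not pass, or 20 and 1 adjusted over the list alone (median 0.42, adjusted p = 3.7e-06, and 0.23 with an estimated correlation). The death receptor FAS and the BH3 protein BBC3 rose by 1.15 ± 0.16 and 0.91 ± 0.13, and the median of p53 targets in siControl 2 was 0.22 above that of siControl 1 and 3. Of the 11 members of the cyclin-dependent kinase inhibitor and senescence list, 8 rose and 3 did not pass, the same adjusted over the list alone (median 0.72, adjusted p = 0.0015, and 0.37 with an estimated correlation). The inhibitor CDKN1B rose by 0.72 ± 0.08, and the median of this list in siControl 2 was 0.39 above the other controls.

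Of 10 luminal prostate markers, 1 rose, 7 fell and 2 did not pass in C4-2, and the counts were 1 and 7 adjusted over the list alone. Their median was -0.41 (adjusted p = 0.00023, and 0.23 with an estimated correlation). KLK3, which encodes PSA, changed by -0.40 ± 0.04 and the membrane antigen FOLH1 by -0.50 ± 0.06. KLK2 at -0.96 ± 0.13 and the cation channel TRPM8 at -1.08 ± 0.14 hold TCACTTG in the 3' UTR. This list's median in siControl 2 was -0.05 against the other controls. Of 25 androgen response genes, 7 rose and 12 fell (8 and 12 adjusted over the list alone, median -0.17, adjusted p = 0.010, and 0.23 with an estimated correlation). The androgen call ended with quantile normalization (adjusted p = 0.097), and without siControl 2 the median was -0.10. Of 25 cholesterol synthesis genes, 14 rose, 2 fell and 9 did not pass, or 15 and 2 adjusted over the list alone (median 0.30, adjusted p = 0.00073, and 0.23 with an estimated correlation). INSIG1 rose by 1.17 ± 0.05 from 163 to 369 TPM, and the list's median in siControl 2 was -0.08 against the other controls. The cholesterol call ended without siControl 2 (adjusted p = 0.072), at a median of 0.29, and with a pseudocount of 5 the median was 0.17. Of 16 fatty acid synthesis genes, 10 rose and 6 did not pass, the same adjusted over the list alone (median 0.30, adjusted p = 0.0029, and 0.23 with an estimated correlation), with the synthase FASN at 0.97 ± 0.10 and a median of 0.15 in siControl 2 against the other controls.

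Of 27 NRF2 targets in C4-2, 16 rose and 11 did not pass, and adjusted over the list alone 18 rose and 1 fell (median 0.26, adjusted p = 2.1e-05, and 0.23 with an estimated correlation). Their median in siControl 2 was 0.18 against the other controls. Of 28 ATF4 targets, 9 rose and 19 did not pass (12 rose adjusted over the list alone, median 0.25, adjusted p = 0.0038, and 0.52 with an estimated correlation). The ATF4 median in siControl 2 was 0.44 against the other controls, and without that library it was 0.38. Of 25 homologous recombination and Fanconi genes, 13 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.33, adjusted p = 0.0049, and 0.43 with an estimated correlation), with 0.32 in siControl 2 against the other controls. Of 13 mitochondrial-genome mRNAs, 7 fell and 6 did not pass (8 fell adjusted over the list alone, median -0.25, adjusted p = 5.2e-05, and 0.37 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.084). Their median in siControl 2 was -0.22 against the other controls. Of 17 heat shock genes, 2 rose and 10 fell (3 and 10 adjusted over the list alone, median -0.20, adjusted p = 0.0019, and 0.34 with an estimated correlation). Their median in siControl 2 was -0.34 against the other controls, and without that library the heat shock median was -0.41. Of 23 glycolysis genes, 2 rose and 8 fell (2 and 10 adjusted over the list alone, median -0.11, adjusted p = 0.0010, and 0.37 with an estimated correlation). Their median in siControl 2 was -0.27 against the other controls, and the glycolysis median was -0.06 without siControl 1, -0.18 without siControl 2 and -0.06 without siControl 3.

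Among lists close to folate metabolism in C4-2, pyrimidine and deoxynucleotide synthesis (adjusted p = 0.23) and the methionine cycle (0.99) were not called. Of 13 purine synthesis genes, 1 rose and 6 fell (3 and 7 adjusted over the list alone, median -0.18, adjusted p = 0.0059, and 0.27 with an estimated correlation). ATIC and PFAS of that pathway changed by -0.49 ± 0.09 and -0.49 ± 0.11. The median of purine genes in siControl 2 was -0.11 against the other controls. Of 26 folate genes, 3 rose and 8 fell (4 and 8 adjusted over the list alone, median -0.10, adjusted p = 0.027, and 0.23 with an estimated correlation). The folate call ended with array weights (adjusted p = 0.068) and without siControl 2 (0.10). MTHFD2 rose by 0.36 ± 0.12 (adjusted p = 0.034), and this was 0.55 without siControl 2 and lost its call without siControl 1 (0.14) or siControl 3 (0.13), and without siMTHFD1L 1, 2 or 3 (0.076, 0.073 and 0.083). MTHFD1 changed by -0.32 ± 0.07 (adjusted p = 0.0071) and holds TCACTTG in its 3' UTR. Of 37 mitochondrial translation genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone, median -0.08, adjusted p = 0.00094, and 0.23 with an estimated correlation). In siControl 2 their median was -0.07 against siControl 1 and 3, where the siMTHFD1L libraries stood at -0.11. The transcription factor TFB2M, at -1.21 ± 0.06, holds TCACTTG, and TFAM, at -0.35 ± 0.07, does not. Of 8 serine synthesis genes, 3 rose (6 adjusted over the list alone, median 0.21, adjusted p = 0.036, and 0.42 with an estimated correlation), a call that ended without siControl 1 (0.074) or siControl 3 (0.069), at a filter of 5 TPM (0.060) and without the trend (0.055). The serine median in siControl 2 was 0.31 above siControl 1 and 3, against 0.32 in the siMTHFD1L libraries. Of 19 DNA and histone methylation genes, 7 rose, the same adjusted over the list alone (median 0.09, adjusted p = 0.046, and 0.37 with an estimated correlation). The methylation call ended without siControl 2 (0.35), siMTHFD1L 2 (0.057) or siMTHFD1L 3 (0.075).

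The mean of both lines asks which changes are shared. Within the same limit of 5 TPM, the largest mean increases were the mitotic kinesin KIF2C at 1.54 ± 0.16 and the mitotic kinase AURKA at 1.49 ± 0.14 (adjusted p = 1.8e-05). They belong to the G2/M list, of whose C4-2 rise siControl 2 alone carried 0.793. FOSB and FOS, subunits of the transcription factor AP-1, changed by -1.95 ± 0.35 and -1.69 ± 0.28. CYB5A (chromosome 18, 74250847 to 74292016) changed by -1.95 ± 0.08 (adjusted p = 3.5e-08), the growth factor TGFB2 by -1.33 ± 0.10, the zinc transporter SLC39A6 by -1.25 ± 0.04 (adjusted p = 3.9e-09) and ADAM9 by -1.19 ± 0.04 (adjusted p = 3.9e-09). FOSB, CYB5A, TGFB2, SLC39A6 and ADAM9 all hold TCACTTG in the 3' UTR. SLC39A6 fell from 26.1 to 10.3 TPM in PC-3 and from 184 to 77.1 in C4-2. The near-identical paralogs FAM72A, FAM72B and FAM72C rose by 1.42 ± 0.16, 1.42 ± 0.19 and 1.40 ± 0.18, and which of them the reads came from is uncertain.

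On average over both lines, 6952 genes were called, 4215 higher and 2737 lower, and 114 changed by at least 1, 93 upward and 21 downward. The balance turned under median-of-ratios factors, with 3454 higher and 3486 lower, and under quantile normalization, with 3326 and 3493. After rescaling without the highest and mitochondrial-genome genes it did not turn, with 3623 and 3190. Across genes, the log2 fold changes of the lines correlated at Pearson r = 0.176 and Spearman rho = 0.124, and genes are not independent replicates. Of 2309 genes called in both lines, 980 rose in both and 526 fell in both, against 649 and 318 if the calls were independent (one-sided Fisher's exact p = 6.0e-53 and 1.7e-36). The other 34.8% moved in opposite directions, with 299 higher in PC-3 and lower in C4-2 and 504 the reverse. These were fewer than the 344 and 600 of independent calls. Fisher's test treats genes as independent, so its p-values can be far too small. With the preset correlation, 21 lists were called, and G1/S genes alone kept the call with an estimated one, at adjusted p = 0.0064. The estimate for the G1/S list was -0.016, below the preset value. That list was not called in C4-2, where 17 rose and 6 fell (19 and 6 adjusted over the list alone, median 0.18, adjusted p = 0.26, and 0.37 with an estimated correlation). The call on the mean thus does not show a shared change, and a smaller rise in C4-2 is not excluded. G2/M genes rose in 40 of 42 cases (41 adjusted over the list alone, median 1.19, adjusted p = 7.2e-21, and 0.21 with an estimated correlation). G1/S genes rose in 31 and fell in 3 of 42 (32 and 4 adjusted over the list alone, median 0.27, adjusted p = 6.3e-07). Cholesterol genes rose in 19 and fell in 2 of 25 (19 and 3 adjusted over the list alone, median 0.29, adjusted p = 8.5e-07, and 0.16 with an estimated correlation). ATF4 targets rose in 20 of 28 (21 adjusted over the list alone, median 0.30, adjusted p = 4.3e-06, and 0.38 with an estimated correlation). Heat shock genes fell in 11 of 17 and 1 rose (12 and 1 adjusted over the list alone, median -0.30, adjusted p = 7.2e-06, and 0.16 with an estimated correlation). Without C4-2 siControl 2, the calls of immediate early genes (adjusted p = 0.010) and methylation genes (0.022) ended at 0.34 and 0.11, and with an estimated correlation they stood at 0.21 and 0.31.

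The difference between the lines asks whether the knockdown acted unlike in PC-3 and C4-2. PTGS2, DIO3, a deiodinase of thyroid hormone, and IL1RL1 rose in PC-3 but not in C4-2. GBP1, an interferon-induced GTPase, fell from 33.7 to 11.1 TPM in PC-3 and rose from 1.83 to 5.13 in C4-2. Of 26 nucleolar genes, 10 rose and 15 did not pass in PC-3 while 21 fell in C4-2, calls of the list that stood at adjusted p = 0.53 and 0.23 with an estimated correlation. The log2 fold change of NPM1, a ribosome assembly chaperone, was 0.59 ± 0.07 higher in PC-3. Of 25 p53 targets, 13 had the higher change in C4-2 and 11 did not pass (adjusted p = 0.27 for the list with an estimated correlation), and the inducible kinase PLK2 differed by -1.18 ± 0.13. In all, 5616 genes differed, 2362 with the higher change in PC-3 and 3254 with the lower, and 508 differed by at least 1, 214 and 294 of them in these directions. Under median-of-ratios factors the counts were 2812 and 2913, and under quantile normalization 2734 and 2819. After rescaling without the highest and mitochondrial-genome genes they were 2285 and 3455.

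Among genes with a mean of at least 5 TPM in any group, the largest differences were DIO3 at 3.23 ± 0.49 (adjusted p = 0.00061) and PTGS2 at 2.77 ± 0.14 (adjusted p = 1.2e-06) upward, and GBP1 at -2.65 ± 0.16 (adjusted p = 2.9e-06) and MS4A7 at -2.16 ± 0.10 downward. With a pseudocount of 5 DIO3 and MS4A7 moved to 1.76 and -1.21. MTHFD1L itself fell further in PC-3, by -0.35 ± 0.11 (adjusted p = 0.036). That call ended without PC-3 siControl 1 or 3 (0.079 and 0.079), PC-3 siMTHFD1L 1 or 3 (0.087 and 0.067), C4-2 siControl 1 or 3 (0.056 and 0.061) and C4-2 siMTHFD1L 3 (0.070), and with quantile normalization (0.15). Of the 36 lists, 16 differed with the preset correlation, and G1/S genes alone with an estimated one (median 0.21, adjusted p = 5.8e-06, and 0.014 with an estimated correlation). Their estimate was -0.016, below the preset value. Nucleolar genes had a median difference of 0.67 (adjusted p = 1.4e-14, and 0.22 with an estimated correlation), with 21 of 26 higher in the PC-3 change (25 adjusted over the list alone). Interferon-stimulated genes had a median of -0.62 (adjusted p = 7.1e-10, and 0.051 with an estimated correlation), with 2 of 32 higher and 24 lower (2 and 27 adjusted over the list alone). Under siControl these genes stood a median of 4.09 higher in PC-3 than in C4-2. Genes of low TPM in C4-2 had little room to fall there, which was not separated from a differing response. Targets of p53 had a median of -0.43 (adjusted p = 0.0011, and 0.27 with an estimated correlation), with 1 of 25 higher and 13 lower (1 and 18 adjusted over the list alone). G2/M genes had a median of 0.63 (adjusted p = 1.2e-06, and 0.57 with an estimated correlation), with 15 of 42 higher. The G2/M median was 0.27 without C4-2 siControl 2.

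**Figure D3:**
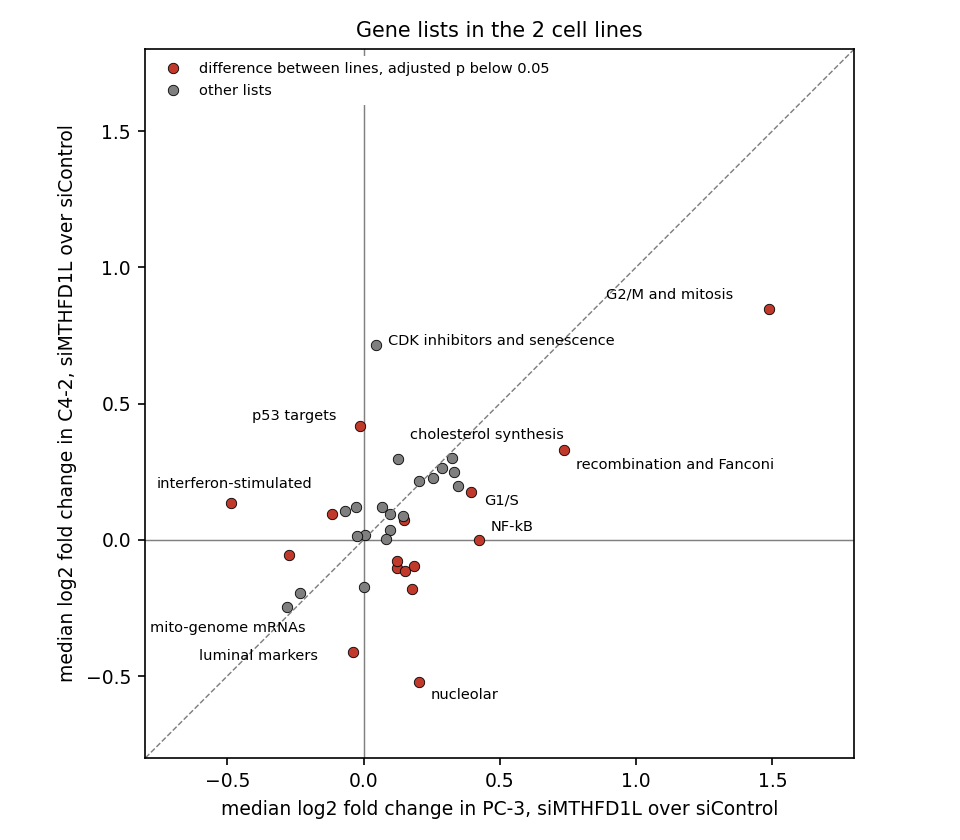
Median log2 fold change (siMTHFD1L over siControl) of each of the 36 lists in PC-3 (horizontal axis) and C4-2 (vertical axis), where red points are the 16 lists whose difference between the lines has an adjusted p below 0.05 and the dashed line marks equal change. Nucleolar genes lie at 0.20 in PC-3 and -0.52 in C4-2, and interferon-stimulated genes at -0.49 and 0.13.

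PC-3 and C4-2 siControl cells were compared to describe the starting states. The genes highest in PC-3 over C4-2 included the keratins KRT81 and KRT7 and the urokinase protease PLAU, at log2 differences of 11.68 ± 0.06, 11.47 ± 0.11 and 10.86 ± 0.05. Of the prostate kallikreins, KLK3 was listed at 0 in PC-3 siControl and stood at 5144 TPM in C4-2, and KLK2 was listed at 0 and stood at 741. In all, 15998 genes differed, 6927 higher in PC-3 and 9071 lower. Of the 11 lists called, interferon-stimulated genes were higher in PC-3 in 31 of 32 cases (median 4.09, adjusted p = 2.7e-14, and 0.016 with an estimated correlation). Androgen response genes were lower in 22 of 25 (median -3.88, adjusted p = 1.2e-07, and 0.016 with an estimated correlation), and mesenchymal genes higher in 21 of 29 (median 1.85, adjusted p = 7.5e-05, and 0.016 with an estimated correlation). Basal markers were higher in 7 of 8 (median 3.19, adjusted p = 0.0024, and 0.089 with an estimated correlation). G1/S genes, whose change also differed between the lines, started lower in PC-3 in 34 of 42 cases and higher in 5. Their median was -0.81 (adjusted p = 0.0012, and 0.020 with an estimated correlation). Whether this starting level set their differing change was not tested.

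Several lists were called by the knockdown in neither line. Adjusted over the list alone, the counts that rose and fell in PC-3 were 9 and 2 of 17 pyrimidine genes, 4 and 6 of 16 methionine cycle genes, 8 and 6 of 22 hypoxia targets and 1 and 1 of 20 genes of the ER unfolded protein response. Over all genes tested these counts were 8 and 2, 4 and 5, 8 and 5, and 2 and 1. In C4-2 the counts over all genes were 6 and 7, 3 and 3, 5 and 6, and 3 and 2. Of 26 apoptosis regulators, 2 rose in PC-3, and 11 rose and 4 fell in C4-2. Of 53 cytosolic ribosomal proteins, 4 rose in PC-3 and 6 in C4-2. Of 13 RNA interference genes, 3 rose and 4 fell in PC-3, and 5 rose and 3 fell in C4-2. The median, the mean and the direction of the test differed in sign for apoptosis regulators in PC-3 (-0.07, 0.01 and down), mesenchymal genes in PC-3 (-0.03, -0.06 and up), RNA interference genes in PC-3 (0.07, 0.01 and down), and epithelial genes in C4-2 (-0.06, 0.03 and down). In C4-2 they also differed for the ER unfolded protein response (0.09, 0.09 and down), basal markers (0.03, 0.01 and down), hypoxia targets (0.0040, 0.0077 and down) and mesenchymal genes (0.01, 0.04 and down). The same happened in uncalled lists of the other comparisons. On average over both lines these were folate, methionine, purine, pyrimidine, mesenchymal, glycolysis, hypoxia, mitochondrial translation and lysosome genes. In the difference between the lines they were mesenchymal, methylation and heat shock genes, and between siControl groups serine and lysosome genes. The p53 list in PC-3 had an upward test beside its median of -0.01.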

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

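The R squared of length and GC was chosen only after the result was seen, and the other tests in this part before. A test of the difference between PC-3 and C4-2 marked 5616 genes for a closer look. Among the largest, the PC-3 change exceeded the C4-2 change by 3.23 for DIO3, 2.77 for PTGS2, 2.49 for FAM220A, 2.46 for ADRA2A and 2.26 for IL1RL1. It lay below it by -2.65 for GBP1, -2.16 for MS4A7, -2.13 for CYP2B6, -2.05 for SHISA3 and -1.98 for HMOX1. In C4-2, PTGS2, IL1RL1, MS4A7 and CYP2B6 changed by only -0.01, 0.05, -0.01 and 0.02, and a gene hardly expressed there can show little change. Among folate enzymes the difference was -0.35 for MTHFD1L, 0.31 for MTHFD1, 0.44 for SHMT2 and 0.41 for SLC25A32. For lists, the PC-3 change minus the C4-2 change was taken per gene, and the median of these differences is given. It was 0.20 for folate genes, 0.35 for purine synthesis, 0.19 for pyrimidine synthesis and 0.21 for G1/S genes. For G2/M genes it was 0.63, for glycolysis 0.27 and for homologous recombination and Fanconi genes 0.35. With an estimated correlation, G1/S genes kept the call (adjusted p = 0.014), and these other lists lost it, at 0.19, 0.19, 0.17, 0.57, 0.34 and 0.47 in the same order. The correlation estimated for G1/S genes was -0.016, below the preset value. Without C4-2 siControl 2, the medians of folate, G2/M, and recombination genes were 0.11, 0.27 and 0.17. Medians differed by 0.67 for nucleolar genes, 0.21 for mitochondrial translation, 0.073 for nuclear respiratory chain genes, 0.14 for NF-kB and cytokine genes and 0.39 for luminal markers, at 0.22, 0.051, 0.48, 0.39 and 0.47 with an estimated correlation. The median difference was -0.43 for p53 targets, -0.62 for interferon-stimulated genes, -0.23 for epithelial genes and -0.15 for lysosome genes, at 0.27, 0.051, 0.28 and 0.47 with an estimated correlation. Several of these list calls rested on a choice of setting or library, among them NF-kB genes (adjusted p = 0.13 without C4-2 siControl 2), luminal markers (0.056 without C4-2 siControl 3) and epithelial genes (0.077 without PC-3 siMTHFD1L 3). PC-3 carries no functional p53, and whether p53 status sets the difference of its targets was not tested.

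Splits of the samples into groups of equal size were counted for each comparison. For both lines together, 100 of the 200 possible splits were drawn. On average over both lines, 1 of 100 splits, the real one, gave at least 6952 genes, and the highest other gave 3661, so chance can be excluded there at 0.05. For the difference between the lines, 1 of 100 drawn gave at least 5616, and the highest other drawn gave 3484. Exchanging siControl and siMTHFD1L in C4-2 alone, a split that was not drawn, turns the difference into the mean and gives 6952, so these splits test for a knockdown effect and decide nothing about a difference between the lines. In PC-3, in C4-2 and between siControl groups, 10 splits exist, so the share cannot go under 0.05. There the real split gave 6323, 5832 and 15998 genes, 1 split in each case, and the highest other split gave 3, 9 and 0.

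Mitotic genes rose after knockdown in both lines, though the list lost its call with an estimated correlation (adjusted p = 0.23 in PC-3 and 0.37 in C4-2). That correlation, 0.84, was estimated over all 12 libraries and so includes the deviation of C4-2 siControl 2. The PC-3 siControl medians lay between 4.28 and 4.32, so the lost call in PC-3 does not measure the spread in PC-3 alone. The level in C4-2 siControl 2 raises the question of whether the state of the wells, not MTHFD1L, set the rise. Scaling of the TPM values was argued against, since the smallest median under the other 3 scalings was 0.916 of the value as deposited. Transcript length and GC together had an R squared of 0.00497 in PC-3 and 0.00836 in C4-2 across genes, so a trend of fold change with either was too weak to carry the rise, and 0.985 of the median remained after regression on both. In C4-2, a state that differed between wells without loss of MTHFD1L may contribute, since siControl 2 alone reached 0.793 of the rise, and in PC-3 the highest control deviation was 0.0319 of it, where a state shared by all wells of a group cannot be told apart from the knockdown. Loss of MTHFD1L stays open as a cause in both lines, because the labels describe no rescue and do not tell siRNAs apart.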

How the results depend on the processing

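Of 608 gene results, 560 kept their direction and their side of the threshold in all settings run for genes, which leave out the threshold of 0.01. These genes were mostly picked for large changes or small p-values in the same data, which favours stability. Of 76 list results 3 did so in all settings, and of 9 counts 1 stayed about the same. At an adjusted p below 0.01, genes changed in PC-3 numbered 4097, genes changed in C4-2 2881, genes changed on average over both lines 4318, and genes whose change differs between the lines 2994. With array weights, 8805 genes were called in C4-2 and 8907 for the difference, where C4-2 siControl 2 had a weight of 0.132 and the others 0.655 to 3.08, and with only the 2 groups compared C4-2 had 2982. Leaving out each library gave 4983 to 5203 genes in PC-3, 3571 to 8766 in C4-2, 5902 to 9195 for the mean, 4419 to 8318 for the difference and 15367 to 16029 between siControl groups. Replicate number as a block gave 5561, 4922, 6188, 4690 and 14474. In C4-2, 65.3% of calls were higher, against 51.0% with median-of-ratios factors, 50.3% with quantile normalization and 60.5% after rescaling. For the mean the share fell from 60.6% to 49.8%, 48.8% and 53.2% in the same order. Median-of-ratios factors moved the median of all genes between siControl groups by 0.142. With an estimated correlation the lists called went from 20 to 1 in PC-3, 19 to 0 in C4-2, where limma's camera gave 0.23 as the lowest adjusted p, 21 to 1 for the mean and 16 to 1 for the difference. The correlation of log2 fold changes between the lines, 0.176, was 0.130 with a pseudocount of 0.1, 0.209 with 5, 0.161 with no filter, 0.212 at 5 TPM, 0.181 with quantile normalization, 0.171 after rescaling, 0.172 with array weights and 0.169 to 0.180 without single libraries. The sign reversed for MTHFD1 in PC-3 without PC-3 siControl 2 (0.0041) and without siMTHFD1L 2 (0.041, in a range from -0.036), MTHFD2L in C4-2 without siControl 1 (0.019, in a range from -0.053), LAMB3 in C4-2 with quantile normalization (-0.0052), SLC25A32 on average with median-of-ratios factors (-0.00016) and quantile normalization (-0.015), and MTHFD2 for the difference without C4-2 siControl 2 (-0.024, in a range up to 0.26), and none of these values had been called. The cause was not tested for these changes.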

Other observations

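The tests of 3' UTR composition and of a wrong label, and the counts of sites in named genes, in lists and in transcripts of MTHFD1L's length, and the R squared of length and GC, were chosen only after the result was seen. Set against siControl 2 alone, a single library with no spread and so no test, the C4-2 siMTHFD1L medians were 0.24 for cholesterol genes, 0.38 for p53 targets, 0.27 for G2/M genes, -0.31 for luminal markers and -0.29 for nucleolar genes. They were -0.0024 for ATF4 targets and 0.015 for glycolysis. In siControl 2 itself, genes of the ER unfolded protein response lay 0.53 above siControl 1 and 3, against 0.27 in the siMTHFD1L libraries. For 4 lists of markers, too few members were expressed to test them. Of 16 neuroendocrine markers 4 were tested, with the highest library value 72.4 TPM for EZH2, which cycling cells also express. Of 10 fibroblast markers 2 were tested (COL1A1, 39.2 TPM), of 13 blood and immune markers 1 (CD68, 44.6 TPM), and of 10 endothelial markers 3 (ROBO4, 11.8 TPM).

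Of 16355 words of 7 bases in 3' UTRs of 12054 genes, TCACTTG had the lowest z in both lines, at -14.3 in C4-2 and -4.74 in PC-3. The overlapping word CACTTGA came next, at -11.5 and -4.10. In PC-3 other words came close in size, such as GAGGCCT at -4.01 and CTGGTCT at 4.49. Genes with TCACTTG differed there by -0.0446 on the log2 scale, and genes with GGCGAGT by -0.0862. Of the genes with an annotated 3' UTR that fell in both lines, 186 of 440 (42.3%) held TCACTTG, against 11.1% of those that rose in both. Of all 12054 genes searched, 2169 held it. The word was picked for the fall of its genes in these data, so an excess follows from the choice, and these shares were not matched for 3' UTR length. The 8-base word TCACTTGA was in 4 of the 10 largest decreases on average over both lines and in 9.91% of all genes searched. CYB5A holds it on chromosome 18 at 74253487 to 74253494 and at 74252935 to 74252942, SLC39A6 on chromosome 18 at 36108898 to 36108905, ADAM9 on chromosome 8 at 39015059 to 39015066, and TGFB2 on chromosome 1 at 218441760 to 218441767. MTHFD1L itself holds TCACTTGA once in its coding sequence, in exon 14 of 28, on chromosome 6 at 150944494 to 150944501. Of 5028 coding transcripts within 10% of its length of 3604 bases, 7.92% hold the word. In C4-2, members with and without TCACTTG had medians of -0.64 and -0.47 in the nucleolar list, -0.70 and -0.18 among luminal markers, and -0.37 and -0.08 in mitochondrial translation. Other lists went the other way, with 0.04 and -0.20 for heat shock genes, -0.06 and -0.15 for glycolysis and 0.49 and 0.22 for ATF4 targets. These lists are examples of each direction and not a tally, few of their members hold the word, and the differences were not tested.

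The decrease of genes with TCACTTG may come from seed pairing of a guide strand of the siRNA against MTHFD1L. The 8-base site went with a change -0.0929 ± 0.0115 below that of the 6-base site in C4-2, as graded seed pairing needs. This cannot decide for seed pairing, because TCACTTG and CACTTGA were picked as the lowest words in these same fold changes. Genes with the 8-base site hold both words and genes with the 6-base site alone hold neither. Alu repeats, which hold the same bases, were argued against as the whole cause. In C4-2, genes without an Alu word still stood at -0.1887 ± 0.0217 with the 8-base site, over 292 genes, and in PC-3 at -0.1246 ± 0.0236. The 903 genes with both the 8-base site and an Alu word stood at only -0.0679 ± 0.0106 in C4-2 and -0.0135 ± 0.0125 in PC-3. MS4A7, CYB5A, MTHFD1, TRPM8, POLR1A and NIP7, named above for TCACTTG, also hold an Alu word. Length and composition of the 3' UTR were argued against as the whole cause in C4-2, where this was tested. The z values were taken after regression on 3' UTR length and GC. The lowest of 419 other words of the same bases reached z = -6.9511 there, against -14.3 for TCACTTG. That word, CACTTGT, itself holds the 6-base site. Because TCACTTG had been picked as the lowest of all words, its rank among these was fixed, and only the size of the gap speaks against composition. The siRNA sequences are not given and the labels do not tell siRNAs apart, so a microRNA with this seed or the loss of MTHFD1L stays open, untested, for each of these genes.

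C4-2 siControl 2 lay between the other controls and the siMTHFD1L libraries, and its deviation was 0.646 of the knockdown effect over all genes. A wrong label was argued against, since its MTHFD1L TPM was 0.968 of that of the other controls, and admixture of siMTHFD1L RNA was argued against, since its 8-base site genes stood at 0.0251 ± 0.0087 where admixture needed -0.0593. Transcript length and GC bias were argued against, since both together had an R squared of 0.0236 for its deviation across genes, whose correlation with the knockdown effect was 0.697 before and 0.712 after regression on them. A growth state that differed between wells stays open. Its G2/M median lay 0.923 above siControl 1 and 3, but this follows from where the library lies, because the list also rose most in the siMTHFD1L libraries, and the labels give no cell density.

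A hypothesis drawn from the same search is that transfected siRNA competes with microRNAs for the silencing machinery. In C4-2 the highest words were TACCTCA (z = 5.6) and CTACCTC (5.5), which pair with let-7, and CAGTATT (4.47), which pairs with miR-200. Sites of 14 abundant families had a mean z 0.958 ± 0.461 above those of 12 restricted families in C4-2, and 0.0399 ± 0.424 in PC-3. The difference between the lines was not tested, and the control siRNA loads the same machinery, so this could only reflect a difference between the siRNAs.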
